A study of Mus musculus with 9 samples.

How the data were processed

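Mature microRNAs were measured on 9 two-colour arrays of 206 probes in mouse embryonic stem (ES) cells of the V6.5 line and in the embryonic fibroblasts used as feeders. Each array carried the RNA of 1 group in 1 channel and RNA of wild-type ES cells in the other, per the labels. The groups were heterozygous DGCR8 knockout cells (3 arrays), homozygous knockout line 1 (2 arrays), homozygous knockout line 2 (2 arrays) and feeder fibroblasts (2 arrays). In each group the dyes of replicate 2 were swapped relative to the other arrays, so that its own RNA lay in channel 1. Per the labels' protocols, small RNA was cut from a denaturing gel, positive control RNAs were added in equal amount, and the RNA was tailed, ligated to capture sequences and hybridised with the NCode labelling system. Per the series text, ratios were normalised on the positive control RNAs, the arrays of a knockout line were duplicate hybridisations, and the heterozygous RNA came from 2 preparations. Which heterozygous arrays share a preparation, the scanner, the image software, the background correction and the rule for leaving out spots are not given in the sources used here.

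The deposited values were log10 ratios. This base was read from the values: on replicate 2 of knockout line 1, all 90 values below the log10 of 0.05 were the log10 of a ratio rounded to 4 decimals, where 3.84% would be by chance, and no such rounding was found with base 2 or e. On the 5 other arrays with values that low, the feeder arrays included, 0 to 4 values fitted such a rounding, near the share by chance, so those values do not show their base. For the other knockout arrays the base rests on slopes between 0.853 and 0.986 among the 4 knockout arrays. For the feeder and heterozygous arrays the same base was assumed, as they stand in 1 table with the knockout arrays, and the feeder folds depend on it. The deposited text cells of replicate 1 of knockout line 1 (2 spreadsheet errors among its values, other unit) and of feeder replicate 1 (1 error), and all null cells, were treated as missing. Log10 ratios were multiplied by 3.3219 to give log2 ratios, with no pseudocount and no further scaling. The direction, own RNA over wild type, is likely rather than stated. It rests on the series text, which names wild type as the reference. Arrays of opposite dye correlated positively across probes within a group, which shows that they share an orientation but not which (Pearson r of 0.922 in line 1, 0.912 in line 2 and 0.962 in the feeders). No pair of arrays held identical values. Heterozygous replicates 2 and 3 had r = -0.05, with nearly all of their ratios close to 0. Scale beyond the control RNAs and centring stay unknown. The medians of the mouse probes, in log2, were -0.18, 0.03 and 0.09 on heterozygous replicates 1, 2 and 3, -6.16 and -5.57 on the arrays of line 1, -4.91 and -5.94 on those of line 2, and 1.34 and 1.16 on the feeder arrays.

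Probe names were matched to mouse microRNA genes of the RefSeq table for GRCm38.p6, used for names only. Of the 206 probes, 195 matched and 11 carried names with no mouse gene, which stayed out of all counts. A value was present on at least 1 array for 155 of the 195, and 58 of the 206 had values on all 9 arrays. The number of probes with a value was 86, 122 and 84 on the heterozygous arrays, 93 and 131 in line 1, 115 and 108 in line 2, and 93 and 133 on the feeder arrays. No spot intensities were analysed here, so signal over background is unknown, and the number of arrays limits the precision.

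The principal comparison used limma 3.58.1 with statmod 1.5.0 in R 4.3.3 (lmFit and eBayes) on 6 values per probe: the 3 heterozygous arrays, the mean of each knockout line's 2 arrays and the mean of the 2 feeder arrays, with a shared spread. Ratios were tested against 0, which leaves out the spread of wild type, since wild-type RNA was only hybridised as the reference. The feeder value was a single value whose spread was borrowed from the other groups. Nothing says that the feeder arrays or the heterozygous arrays were separate cultures, so their p-values measure the spread between arrays, which may be technical. Probes needed values on 2 heterozygous arrays, in both lines and on 1 feeder array, which left 87 probes, 20 of them with a line or feeder mean resting on 1 array. P-values were adjusted by Benjamini and Hochberg over these 87 probes, with a threshold of 0.05. The lines were compared with each other with all 9 arrays as single values, so that comparison covers the spread of hybridisation only. Probe lists written down before the data were examined were tested with limma's camera (preset correlation of 0.01, and an estimated correlation beside it) and fry, adjusted over the lists of at least 3 tested members and the 3 comparisons with wild type. The lists were the mir-290, mir-302, mir-17 family and Dlk1-Gtl2 clusters, the let-7 family, microRNAs of fibroblasts, neurons, muscle, blood, epithelium, and liver and pancreas, and microRNAs made without DGCR8 in later work. On simulated data with 10 of 87 probes changed, the fit recovered 1.5%, 75.1% and 96.6% of changes of 1, 2 and 4 log2 units in the knockout, 16.4%, 80.2% and 97.7% in the heterozygous cells and 0%, 40.4% and 90.9% in the feeders, with at most 0.93 false calls on average. The simulated arrays were independent. Their lines had no spread beyond that of arrays and their heterozygous arrays shared no RNA, so recovery in the data may be lower.

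MicroRNAs were named by a rule fixed with the tests. Per comparison, it took up to 10 probes with the most negative and 10 with the most positive mean among those past the threshold with the same direction on every array of the group. If none passed, the 3 lowest and 3 highest were given as values. It added up to 4 members of each list and the 5 probes highest in the knockout. The alternatives were median centring of each array, the arrays as single values, with and without a random block for line or culture, a dye term, the replicate number as a block, probes with complete values, robust eBayes, a 2-fold rule, averaging heterozygous replicates 1 and 2, and leaving out each array. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 made the tables and plots. The array carried no probe for the Dgcr8 transcript, so the genotypes rest on the labels.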

Results

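DGCR8 is the RNA-binding partner of the nuclease Drosha, and the pair cuts primary transcripts into microRNA hairpins. Ratios of mature microRNAs over wild-type cells were collected from V6.5 mouse ES cells lacking 1 Dgcr8 copy (heterozygous, 3 arrays), from 2 ES lines lacking both copies (2 arrays each) and from the embryonic fibroblasts used as feeder layer (2 arrays). The arrays held values for 84 to 133 of 206 probes, and 87 mouse microRNA probes entered the tests. All ratios are log2 of own RNA over wild-type RNA, a direction that is likely rather than stated, on the scale set by the added control RNAs.

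The first comparison asked how far the microRNA content depended on DGCR8. In the homozygous knockout 78 of the 87 microRNAs were lower than in wild type, 2 were higher and 7 did not pass the test (limma, adjusted p at or below 0.034 for those lower). The median log2 ratio was -5.98, a 63.2-fold reduction, and 71 microRNAs were reduced more than 10-fold and 31 more than 100-fold. The lowest ratio was that of miR-291-3p (-8.01 ± 0.18, SD, n = 2 lines), followed by miR-295 (-7.88 ± 0.07), both from the mir-290 cluster that dominates the microRNAs of mouse ES cells. Next came miR-106a (-7.86 ± 0.24) and miR-17-5p (-7.81 ± 0.13), which belong to clusters that promote proliferation. The other microRNAs of the lowest 10 were miR-376a (-7.79 ± 0.92), miR-293 (-7.76 ± 0.06), miR-292-5p (-7.68 ± 0.06), miR-92 (-7.65 ± 0.27), miR-20 (-7.58 ± 1.03) and miR-15b (-7.55 ± 0.35).

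All 8 tested members of the mir-290 cluster fell in the knockout (median -7.52), from miR-291-3p to miR-291-5p (-6.59 ± 0.47) and miR-290 (-6.80 ± 0.41), and they were also called lower after centring each array. All 10 members of the mir-17 family clusters fell (median -7.14), the least reduced being miR-106b (-4.24 ± 0.53) and miR-25 (-6.29 ± 0.35), and after centring 8 of them were called lower and 1 higher. The 17 microRNAs of the Dlk1-Gtl2 cluster, an imprinted region, fell as well (median -6.19), with miR-127 (-7.44 ± 0.27) near the lower end and miR-341 (-2.83 ± 0.74) and miR-323 (-2.90 ± 0.28) at the upper end. After centring, 8 of the 17 were lower and 3 higher. Of 11 fibroblast microRNAs, 9 fell (median of the list -5.46), among them miR-23b (-6.29 ± 1.42) and miR-23a (-6.28 ± 0.91), but the direction of the list turned with centring (median 0.17), with none lower and 3 higher. The 3 epithelial microRNAs miR-200a (-6.06 ± 0.10), miR-200b (-6.06 ± 1.30) and miR-141 (-4.66 ± 2.00) fell, as did the neural miR-124a (-6.24 ± 0.95) and miR-7 (-5.84 ± 0.44) and the lymphocyte microRNA miR-150 (-5.78 ± 0.76), and none of these 6 was called after centring. The same counts were obtained for these lists when p-values were adjusted over the list alone. The adjusted p of limma's fry, for members moving one way, lay between 5.26e-05 and 0.00104 for the mir-290, mir-17 family, Dlk1-Gtl2, fibroblast and neural lists. Fry tests a list against no change, where 78 of all 87 microRNAs were lower, and used only members with complete values (13 of 17 Dlk1-Gtl2 and 8 of 11 fibroblast microRNAs). Against the other probes none of these lists stood apart, with camera adjusted p from 0.132 (mir-290) to 0.787 (neural) at the preset correlation.

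The let-7 family, which accumulates as stem cells differentiate, stood apart from the other microRNAs. Its 4 tested members had a median of -0.23, against -6.05 for the other probes (camera, adjusted p = 0.000111, preset correlation). Only let-7e was called lower (-0.79 ± 0.53, adjusted p = 0.034), and none was with adjustment over the list alone. Let-7e was no longer called without replicate 2 of line 1 (-0.70), without replicate 2 of line 2 (-0.56), or with heterozygous replicates 1 and 2 averaged. Let-7b (-0.27 ± 0.07), let-7a (-0.19 ± 0.02) and let-7f (0.48 ± 0.58) did not pass the test, while after centring the family's direction turned and all 4 were called higher (median 5.41). All let-7f values given come from 1 probe. Another let-7f probe had no value on any knockout array and was not tested, with a feeder mean of 5.86. With 1 member measured on all arrays, no correlation within the list could be estimated. The other microRNAs that did not pass were miR-138 (-0.52 ± 0.10), miR-99b (-0.25 ± 0.20), miR-99a (-0.08 ± 0.11) and miR-125b (-2.18 ± 3.45). MiR-138 was called lower without heterozygous replicate 3 (-0.52) and without replicate 1 of line 2 (-0.59). MiR-125b was called lower with the arrays as single values (-2.99), with line or culture as a random block (-3.40) and with a dye term (-3.04).

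The microRNAs higher in the knockout were miR-320 and miR-126*. MiR-320, whose hairpin was found in later work to be made without DGCR8, had a ratio of 1.46 ± 0.17 (SD, n = 2 lines), or 2.74-fold over wild type, with an adjusted p of 0.00042, and was above 0 on all 4 knockout arrays. It was the only tested member of the list of microRNAs made without DGCR8. MiR-126* had a ratio of 1.06 ± 0.28 (adjusted p = 0.00854) and was also above 0 on all 4 arrays, and it was not tested when feeder replicate 2, its only feeder value, was left out. Whether a ratio lies above 0 depends on the control RNA scale: after centring each array, which moved the median of the knockout ratios from -5.98 to -0.34, or by 5.64, 33 microRNAs were called lower and 25 higher in place of 78 and 2.

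**Figure D1:**
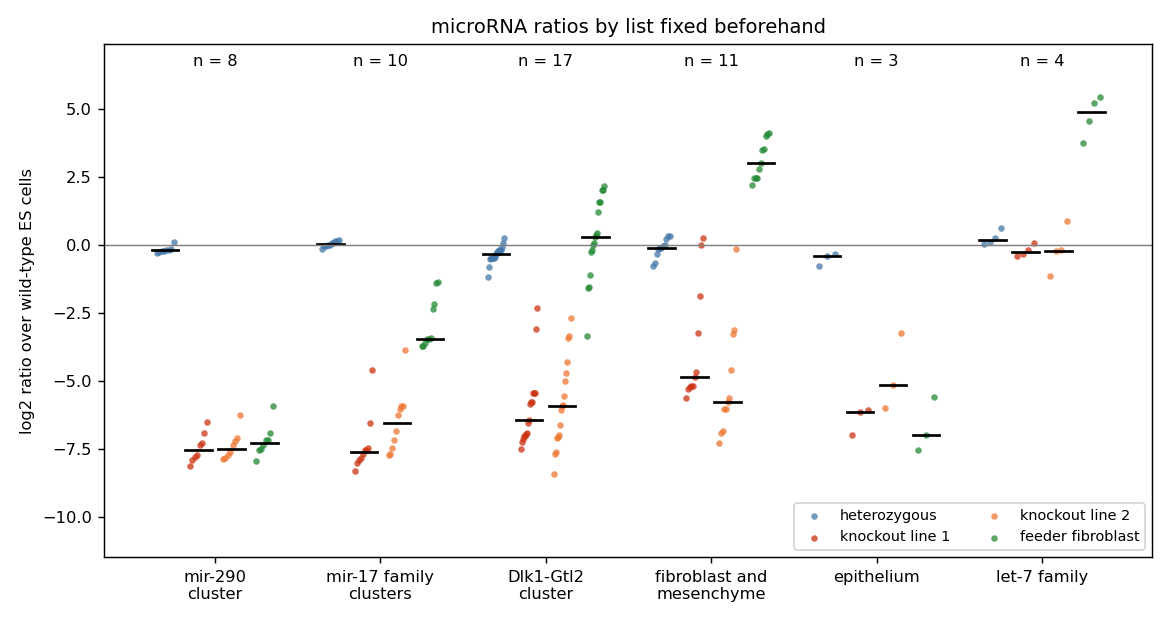
Log2 ratio over wild-type ES cells (vertical axis, control RNA scale) of each tested microRNA (points, n per list) of 6 lists, as the mean of the arrays of heterozygous cells, knockout line 1, knockout line 2 and feeder fibroblasts, with black bars for medians. The mir-290 cluster lies near -7.5 in both lines and in the feeders, while the let-7 family lies near 0 in the lines and at a median of 4.90 in the feeders; after centring, the let-7 and fibroblast medians of the knockout turn to 5.41 and 0.17.

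The 2 knockout lines were independent and were compared to ask whether they lost the same microRNAs. Ratios correlated across the 87 microRNAs with r = 0.911 (Spearman rho = 0.861, across microRNAs, which are not independent replicates), 82 microRNAs were below 0 in both lines and 65 differed by less than 2-fold. No microRNA passed the test between the lines (limma, 0 of 87), and 13 had an unadjusted p under 0.05, 11 of them higher in line 2. The lowest adjusted p were those of miR-370 (-5.76 in line 1 and -3.43 in line 2, adjusted p = 0.054), miR-125b (0.26 and -4.62, adjusted p = 0.064) and miR-141 (-6.07 and -3.25, adjusted p = 0.064), all chosen after their values were seen. MiR-125b had a value on only 1 array of line 1. Of the 11 fibroblast microRNAs, 10 were lower in line 2 than in line 1, against 18 of the 76 other microRNAs, a count taken after the values were seen. The medians of the fibroblast list were -4.87 in line 1 and -5.76 in line 2. The median difference of the list, line 2 less line 1, was -0.30 between the replicates 1 and -2.20 between the replicates 2, where that of all 87 microRNAs was 0.78 and -0.15. Other lists lay higher in line 2, with 10 of 10 of the mir-17 family clusters, 3 of 3 epithelial and 3 of 3 neural microRNAs. These tests cover the spread of hybridisation, with 2 arrays per line.

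**Figure D2:**
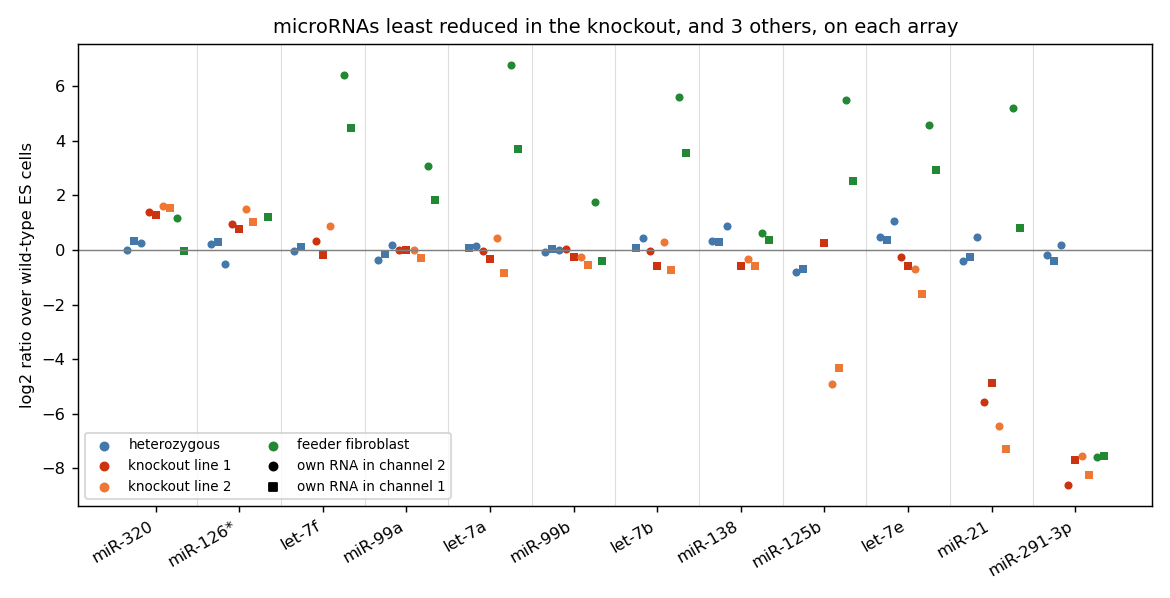
Log2 ratio over wild-type ES cells (vertical axis) on each of the 9 arrays, for the 9 microRNAs not called lower in the knockout and for let-7e, miR-21 and miR-291-3p, with colours for the group and symbols for the channel of its own RNA. MiR-320 lies above 0 on all 4 knockout arrays, the difference of miR-125b between the lines did not pass the test, and the feeder arrays differ from each other most for miR-21.

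The heterozygous cells addressed whether loss of 1 copy changed microRNA levels. No microRNA was called changed in them (limma, 0 lower and 0 higher of 87), and 7 had an unadjusted p under 0.05, 5 lower and 2 higher. The median ratio was -0.05, and 86 of the 87 microRNAs lay within 2-fold of wild type. The lowest values were those of miR-341 (-1.20 ± 0.34, SD, n = 3 arrays, limma adjusted p = 0.31), miR-381 (-0.79 ± 0.55, n = 3) and miR-200a (-0.79 ± 0.69, n = 2). The highest were miR-140 (0.71 ± 0.15, n = 2), miR-150 (0.63 ± 0.18, n = 2) and let-7e (0.63 ± 0.37, n = 3). Without replicate 2 of knockout line 1, which shares in the estimate of the spread, miR-341 was called lower. With 10 of 87 microRNAs changed in simulated data, changes of 2 log2 units were recovered in 80.2% of cases and of 1 unit in 16.4%. The simulation took the 3 heterozygous arrays as independent, although their RNA came from 2 preparations.

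As a list, the Dlk1-Gtl2 cluster was lower in the heterozygous cells than the other microRNAs, with a median of -0.34 against -0.00 (camera adjusted p = 0.000111, and adjusted p = 7.81e-05 with an estimated correlation). The estimate was -0.029 and was taken as 0, so the latter p allows for no correlation among members. With the 9 arrays as single values the estimate was 0.124 and the camera adjusted p was 0.0374. No member passed on its own, also with adjustment over the list alone, and 15 of the 17 had a mean below 0. Fry, which tests the cluster against no change and not against the other microRNAs, gave an adjusted p of 0.0113, and 0.0699 with the 9 arrays as single values. Both fry and the estimated correlation used only members with complete values, 13 of the 17 in the main fit and 9 with single arrays. The median of the cluster less that of the other tested microRNAs was -0.35, -0.39 and -0.44 on replicates 1, 2 and 3, and its direction was kept after centring (median -0.32). The heterozygous medians of the other lists were -0.20 for the mir-290 cluster, 0.04 for the mir-17 family clusters, 0.19 for the let-7 family, -0.11 for the fibroblast list, -0.07 for the neural list and -0.39 for the epithelial list, with camera adjusted p between 0.0671 and 0.836.

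Set directly against the heterozygous cells, where the wild-type reference cancels, 79 microRNAs were lower in the homozygous knockout, 2 were higher and 6 did not pass (limma, 87 tested). The lowest differences were those of miR-15b (-7.91), miR-291-3p (-7.87), miR-106a (-7.86), miR-17-5p (-7.82) and miR-92 (-7.73), followed by miR-295 (-7.67), miR-293 (-7.53), miR-20 (-7.52) and miR-376b (-7.50). MiR-292-5p completed the lowest 10. MiR-320 (1.26, adjusted p = 0.00323) and miR-126* (1.05, adjusted p = 0.025) were again higher, and without feeder replicate 2, the only feeder array with a value for miR-126*, miR-126* was not tested and 1 microRNA, miR-320, was higher. The direction of the Dlk1-Gtl2, fibroblast, let-7 and epithelial lists turned with centring in this comparison, to medians of 0.16, 0.24, 5.28 and 0.04. The 6 that did not pass were let-7a, let-7b, let-7f, miR-99a, miR-99b and miR-125b. After centring, which moved the median from -5.84 to -0.25, 27 were lower and 23 higher.

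Feeder fibroblasts were profiled because the ES cells had been grown on them, to ask whether signal left in the knockout stems from carried-over feeders. In feeders 32 of 87 microRNAs were lower than in wild-type ES cells and 32 were higher. The lowest were those of the mir-290 cluster, miR-293 (-7.95 ± 0.14, SD, n = 2 arrays), miR-291-3p (-7.56 ± 0.02), miR-292-5p (-7.52 ± 0.52), miR-295 (-7.37 ± 0.70), miR-294 (-7.19 ± 0.92), miR-291-5p (-7.17 ± 0.52) and miR-292-3p (-6.90 ± 0.87), together with the epithelial miR-200a (-7.53, 1 array) and miR-200b (-6.98, 1 array) and miR-183 (-7.09 ± 0.34). The highest were let-7f (5.44 ± 1.36), let-7a (5.23 ± 2.19), let-7b (4.57 ± 1.46), miR-29b (4.11 ± 1.35), miR-125a (4.10 ± 0.60), let-7e (3.75 ± 1.18), miR-22 (3.55 ± 2.26), miR-31 (3.49 ± 0.55), miR-181a (3.32 ± 1.22) and miR-21 (3.00 ± 3.11). Without feeder replicate 1, miR-21 was at 0.81 and was no longer called, and without heterozygous replicate 2, where 68 microRNAs could be tested, 20 were higher.

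All 8 members of the mir-290 cluster (median -7.28), all 10 of the mir-17 family clusters (median -3.45) and the 3 epithelial microRNAs (median -6.98) were lower in feeders, as were miR-124a, miR-7 and miR-150. The 4 let-7 members were higher (median 4.90, camera adjusted p = 0.02), as were 9 of the 11 fibroblast microRNAs, or 10 with adjustment over the list alone (median 3.00). Camera set the mir-290 cluster (adjusted p = 0.000111), the mir-17 family clusters (adjusted p = 0.00284) and the fibroblast list (adjusted p = 0.00174) apart from the other probes. With an estimated correlation the adjusted p were 0.24, 0.552 and 0.24. In the Dlk1-Gtl2 cluster 3 microRNAs were lower and 6 higher (median 0.29), and with centring the direction turned (median -0.96), with 8 lower and none higher. Centring moved the feeder median from 0.15 to -1.04, or by -1.19, with 43 microRNAs then lower and 12 higher, and kept 5 of the 11 fibroblast microRNAs as higher. The feeder value rests on arrays of 1 group with no separate culture named.

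The microRNAs highest in the knockout were then set against their feeder values. MiR-320 had 1.46 in the knockout and 0.57 in feeders, where it did not pass the test, lay at -0.68 after centring and at -0.04 without feeder replicate 1, and was called higher without feeder replicate 2 (1.18). MiR-126* had 1.06 and 1.22, let-7f 0.48 and 5.44, miR-99a -0.08 and 2.46, and let-7a -0.19 and 5.23. All 9 microRNAs not called lower in the knockout had a mean feeder ratio above 0. Of the 78 called lower, 38 did (Fisher's exact test, two-sided, p = 0.00319). These calls share the wild-type reference. With calls of the knockout over heterozygous cells, where the reference RNA cancels, the counts were 8 of 8 and 39 of 79 (p = 0.0067, Fisher's exact test, two-sided). The heterozygous cells lay within 2-fold of wild type for 86 of the 87 microRNAs. The level of a microRNA in ES cells thus still enters both ratios, and the repeat is no independent support. On feeder replicate 2 alone miR-99b lay at -0.39 and miR-320 at -0.04, and after centring members such as miR-320 and miR-138 lay below 0. Both tests take microRNAs of 1 family, such as let-7, as independent. Among the 32 microRNAs higher in feeders, 27 were called lower in the knockout (median of the 32, -5.47, a 44.2-fold reduction), and among the 32 lower in feeders all 32 were (median -6.86, a 116-fold reduction). On the deposited scale miR-126* alone was called higher in both, and in feeders it was not called with the arrays as single values (1.22), with a dye term (1.23) or after centring (0.06). After centring, all 4 let-7 members were called higher in both.

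Across the 87 microRNAs the knockout and feeder ratios correlated with r = 0.49 and rho = 0.512, and the covariance was 4.14. Both ratios share the wild-type reference. Groups simulated with no change against a shared reference gave a mean r of 0.35 and a covariance of 0.106. The simulated reference varied across microRNAs with an SD of 0.326, that of the heterozygous means. The knockout median was -5.98, so this setting does not show how much the level in wild-type cells adds to the observed r or covariance. With the knockout over heterozygous cells in place of wild type r was 0.474, which leaves the level in ES cells in both ratios. The knockout signal of the 9 fibroblast microRNAs called lower was 0.131% to 0.977% of the feeder signal, with a median of 0.232%. The corresponding percentages were 2.34% for let-7a, 3.47% for let-7b, 3.2% for let-7f, 17.2% for miR-99a, 49.5% for miR-138 and 52% for miR-99b. These percentages rest on the mean of both feeder arrays. With feeder replicate 1 alone the lowest let-7 percentage was 0.801% and the fibroblast median 0.137%, and with feeder replicate 2 alone they were 6.25% and 0.67%. The lowest of miR-99a, miR-99b and miR-138 was then 11.1% and 26.5%.

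**Figure D3:**
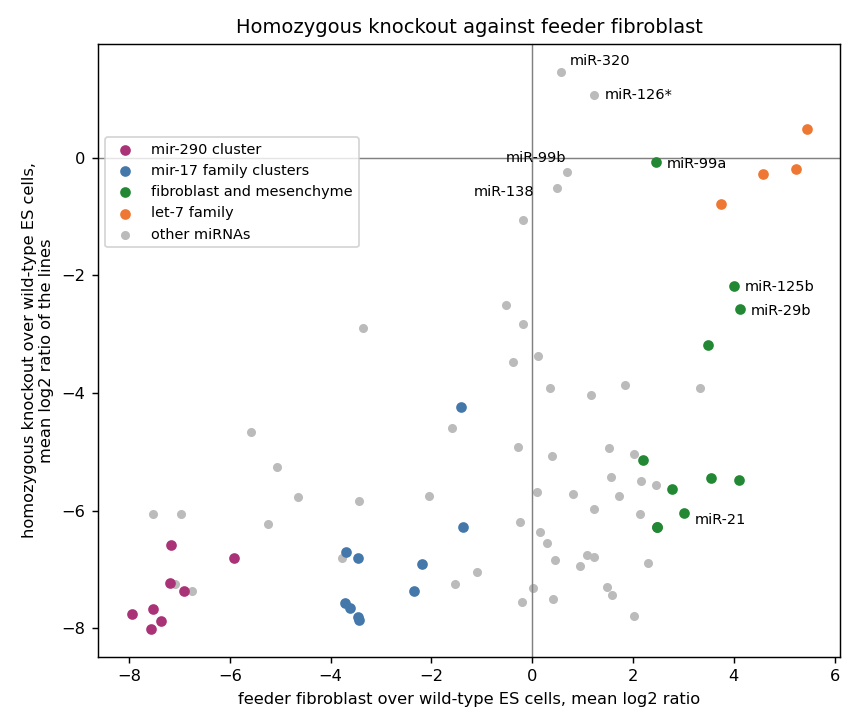
Mean log2 ratio over wild-type ES cells in the homozygous knockout (vertical axis, mean of the lines) against that in feeder fibroblasts (horizontal axis), with 1 point for each of 87 microRNAs on the control RNA scale and colours for 4 lists. The let-7 members lie near 0 in the knockout and between 3.75 and 5.44 in feeders, whereas fibroblast microRNAs such as miR-21 lie above 0 in feeders and far below 0 in the knockout; after centring, the let-7 and fibroblast medians of the knockout turn above 0.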

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

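Probes whose names have no mouse gene were outside every comparison, and a pair of them gave knockout ratios outside the range of the heterozygous arrays. MiR-371 had a mean log2 ratio of -6.26 on the 4 knockout arrays (-7.33 to -4.47), against -1.03 to 0.42 on the 3 heterozygous arrays. MiR-422a had a mean of -1.08 on 3 knockout arrays, against 0.53 and 0.59 on 2 heterozygous arrays.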

How the results depend on the processing

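The named microRNAs, list members included, kept their direction and their side of the threshold in 1244 of 1295 cases over the alternatives. Cases in which an alternative could not test the microRNA were left out of the 1295. Centring accounted for 29 of the 51 exceptions. With it, 13 values with a call on either side turned: against wild type let-7a (5.45), let-7b (5.37), let-7e (4.86), miR-99a (5.57), miR-99b (5.39), miR-138 (4.97), miR-106b (1.40), miR-141 (0.99), miR-323 (2.74) and miR-341 (2.81), and against the heterozygous cells let-7a (5.40), let-7b (5.17) and miR-99b (5.38). The 22 other exceptions included miR-21 in feeders (0.81 without feeder replicate 1), and miR-341 in the heterozygous cells, newly called at -1.20 without replicate 2 of knockout line 1. Centring each array changed the counts most: 33 lower and 25 higher in the knockout, 27 and 23 against the heterozygous cells, and 12 higher in feeders. This follows from its construction, since it sets the median of each array to 0. With values required on all 9 arrays (58 probes tested), 1 was higher in the knockout, 1 against the heterozygous cells and 19 in feeders, fewer probes being tested. A 2-fold change on every array left 1 higher in both knockout comparisons. Against wild type miR-126* lay at 0.95 and 0.78 on the arrays of line 1, short of the 1 log2 unit that this rule needs. An alternative chosen after seeing the data, the 2 lines alone with any probe valued in both, called 101 of 113 lower and 1 higher; the cause was not tested. Leaving out each array gave 0 to 1 lower in the heterozygous cells, 1 to 2 higher in the knockout and against the heterozygous cells, and 20 to 37 higher in feeders, 20 without heterozygous replicate 2 with 68 probes tested. With the replicate number as a block, 78 were lower and 2 higher in the knockout, 76 and 1 against the heterozygous cells, 32 and 33 in feeders and 0 in the heterozygous cells and between the lines. The block left miR-126* without a call against the heterozygous cells (0.79) and in feeders (1.31), and called miR-125b lower in the knockout (-3.04). Differences between replicates 1 and 2 correlated between groups with r from 0.0354 to 0.415, over 0.1 in 4 of 6 pairs of groups but not in the others. With no label naming what a number shares, the numbers were not taken as pairs, and since replicate 2 is also the dye-swapped array, a shared effect of the number cannot be separated from dye. Knockout and feeder ratios correlated with r of 0.551 for line 1 alone, 0.405 for line 2 alone, 0.477 and 0.512 for arrays of different dye, and 0.412 without the mir-290 cluster, an alternative chosen after seeing the data. Signal over background is unknown, so how far background limited the lowest knockout ratios, and the order among them, is unknown.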

Other observations

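All tests of explanations in this part were chosen after the values were seen. Outside the tested probes, 22 mouse microRNA probes had a value on a feeder array and on no knockout array, and all 22 lay above 0 in feeders. They included 9 of the fibroblast list and 3 of the let-7 family, among these the let-7f probe that was not tested. MiR-199a (5.88), miR-214 (4.98) and miR-143 (4.63), all abundant in mesenchymal cells, were valued on both feeder arrays, as was let-7i (5.32). A further 26 untested probes had values in both knockout lines, and 25 of them were below 0 (median -4.46). Among them were miR-302a (-5.68) and miR-302c (-3.74), from a cluster active in pluripotent cells. MiR-340 was the exception, at -0.08 in line 1 and 1.27 in line 2. Let-7g (-2.35) and let-7d (-1.18) were lower than the tested let-7 members. No muscle or liver and pancreas probe was tested.

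In the first pattern, let-7a, let-7b, let-7f, miR-99a, miR-99b, miR-138 and miR-125b did not pass as lower in the knockout, while their mean feeder ratios were above 0. Feeder cells carried over would bring all of their abundant microRNAs. On the means of the arrays, the lowest knockout signal of miR-99a, miR-99b and miR-138 was 17.2% of the feeder signal, against a median of 0.232% for the 9 fibroblast microRNAs called lower. With each feeder array alone it lay 4.74 and 4.65 SD of those microRNAs above their median. The 9 were chosen by their knockout calls, which left out miR-99a and miR-125b of the same list, so these distances are no test. Each of the 9 still bounds what carry-over could bring. Their highest value was 0.744% with feeder replicate 1 and 1.87% with replicate 2, against 11.1% and 26.5% for the lowest of miR-99a, miR-99b and miR-138. These values argue against carry-over as the whole source for those microRNAs. The lowest value of let-7a, let-7b and let-7f also exceeded the highest of the 9, at 2.34% against 0.977% on the means (3.11 SD above their median). With feeder replicate 2 it was 6.25% against 1.87%. With feeder replicate 1 the margin was narrow, at 0.801% against 0.744% (1.90 SD above the median). Of 8 pairs of a knockout and a feeder array, 6 had the lowest let-7 value above every valued member of the 9. The untested let-7g and let-7d were at 0.691% and 1.76%. Carry-over therefore stays open for let-7a, let-7b and let-7f. It also stays open for miR-125b, at 0.254% in line 2 and 7.48% in line 1, the latter from 1 array. Signal near background in both channels may also pull ratios to 0 and stays open: 4 of the 7 lacked a heterozygous value, against 17 of the 78 called lower (Fisher's exact test, two-sided, p = 0.0596), and maturation without DGCR8 was not tested.

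In the second pattern, miR-320 and miR-126* were higher in the knockout. Their knockout signals were 185% and 89.5% of the feeder signals, which argues against carry-over. Signal of the miR-126* probe that does not come from its hairpin is a candidate explanation, since the other arm, miR-126, was at -4.51 (-5.42 and -3.61 on the 2 knockout arrays with a value), while miR-126* lay between 0.78 and 1.48 on 4 arrays. An offset in array scaling could raise both and stays open. The lower of the pair lay 1.31 above the median of the 7 microRNAs that did not pass, whose SD was 0.83. An offset would shift the pair and the 7 alike, so this gap cannot test it. That miR-320 is made without DGCR8 remains an untested hypothesis here.

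In the third pattern, the Dlk1-Gtl2 cluster was lower than other microRNAs in the heterozygous cells. Fewer feeder cells in that culture would lower feeder-rich microRNAs outside the cluster too, but the 26 that were higher in feeders had a heterozygous median 0.0673 above that of the 44 others outside it (bootstrap SE 0.08), which argues against this as the whole source. An effect of lower DGCR8 dose stays open: the 61 others called lower in the knockout had a median 0.313 above the cluster, which restates the pattern and decides nothing. A single array or dye is argued against by the 3 per-array gaps, of which the one nearest to 0 was -0.353. A difference of the imprinted region between the heterozygous clone and the wild-type reference cells may be the source and was not tested.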
